A study of Mus musculus with 6 samples.

How the data were processed

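RNA sequencing was analysed for 6 libraries of primary haematopoietic cells from mouse bone marrow, 3 transduced with an empty vector and 3 with the RUNX1-RARA fusion. Groups were taken from the genotype label of each sample, and table columns were tied to samples by the column names the labels quote. Per the labels' protocols, total RNA was extracted with TRIzol, RNA-seq libraries were made with a commercial kit and sequenced on an Illumina instrument. The labels describe poly(A) selection on oligo(dT) beads beside an m6A-seq tag and do not say whether it applied to the RNA-seq libraries.

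The deposited values were FPKM, that is fragments per kilobase of gene scaled to the mapped fragments of the library, computed by the authors and rounded to 3 decimals. The table listed 21684 Ensembl mouse gene IDs, and every column of sample values in it was used. Per the submitters' processing notes, fastp 0.22.0, HISAT2 2.2.1, featureCounts 2.0.1 and DESeq2 1.32.0 were used, and the builds hg38 and mm10 were named, without the role of each. The annotation release, the strand setting and the treatment of reads that map to several genes are not given in the sources used here. Whether the human fusion transcript could be aligned is not given either. Reads shared by near-identical genes could therefore have been split or dropped, so Hbb-bt, the Ear genes, Chil3, the Ly6 genes and the mitochondrially encoded genes (which have nuclear copies) are uncertain in level. Of the named genes, Gp1bb overlapped Septin5 and Gm49601, mt-Co3 overlapped mt-Atp6 and mt-Nd4l overlapped mt-Nd4 on the same strand. Ddit3 overlapped another ID of its own symbol on the same strand. Csf1r, Prtn3, Cebpb, Nusap1, Ncf1, Ankrd37, Gnl3 and Mettl3 overlapped a gene on the opposite strand. Ddit3 and Aldoa were among 19 symbols with more than 1 ID, and for these the ID with the higher mean FPKM was used. The 78 genes without a symbol were kept under their IDs.

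FPKM depend on the sum of all fragments in a library, so a few very abundant genes can shift all others, and they hold no counts. Read depth was estimated from the steps between low values, since FPKM multiplied by gene length is a whole multiple of the value of 1 read. Exon lengths came from GENCODE M21 on GRCm38 (mm10), in which 21591 of the IDs were found. The estimates were 89.8, 40.8 and 33.1 M reads for empty vector replicates 1, 2 and 3, and 26.6, 27.7 and 40.5 M reads for RUNX1-RARA replicates 1, 2 and 3, a 3.38-fold range. Between 81.8% and 86.4% of low values then lay within 0.1 of a whole number of reads, against 20% by chance. Even numbers made up 66.6% to 71.1% of these, so both reads of a pair may have been counted, and only the relative depths are firm. Because not nearly all values came out whole, reads were not reconstructed and no count test was run. For a transcript of 2 kb, 1 read was worth between 0.0056 and 0.0188 FPKM, so levels under about that size rest on single reads.

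The planned analysis used limma 3.58.1 in R 4.3.3. Genes with at least 1 FPKM in 3 or more of the 6 libraries were tested (10901 of 21684). A linear model with a group term was fitted to log2(FPKM + 1) with trended empirical Bayes moderation, and Benjamini-Hochberg adjusted p-values under 0.05 were called. Log2 fold changes are RUNX1-RARA minus empty vector on the log2(FPKM + 1) scale, with the standard error (SE) of the fit, and they understate the change of low genes. Levels are mean FPKM ± SD over 3 libraries, and folds written as such are ratios of mean FPKM. The labels do not say that replicates came from separate mice or cultures, so the p-values measure only the spread between these libraries, which may be technical. Over genes with at least 1000 estimated fragments (pairs of reads), the median squared difference between replicates was 3.09 to 13.0 times the sampling noise that the estimated depths give. No replicates were merged, and since these depths are not firm the ratio is rough and does not show where the replicates came from.

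Before the data were examined, 29 gene lists were fixed, covering myeloid, lymphoid and other blood lineages, stromal cells, retinoic acid and RUNX1 targets, proliferation, stress and metabolism. The 27 lists with at least 3 tested members were tested against all other genes with limma's camera (preset inter-gene correlation 0.01), adjusted over lists, and again with an estimated correlation. Ddx58 and Vpreb1 of the lists were matched by ID to the symbols Rigi and Vpreb1a. Ahsp was not matched and was not analysed here.

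Genes named in the text followed a rule fixed at the same time. It took Runx1 and Rara, the 8 largest rises and 8 largest falls among called genes whose groups did not overlap and whose mean was at least 5 FPKM in the higher group (predicted or unnamed symbols passed over), and up to 3 called members with the largest change from each list. Lists with fewer than 3 tested members were only counted, and genes in several lists counted under each. Genes named outside this rule are marked as chosen after their values were seen. A few genes that the rule or the lists take are not reported here by name.

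The limma and camera steps and the scaling factors were tested on simulated data. In 20 draws of the comparison of RUNX1-RARA with empty vector (median of 10742 genes fitted, 200 changed), 29.9% of genes changed 1.2-fold, 94.0% of those changed 1.5-fold, 97.8% of those changed 2-fold and 98.0% of those changed 4-fold were called in the right direction. False calls made up 6.35% of calls on average (range 4.19% to 11.5%), a little over the nominal level. Of 20 simulated lists with raised genes 20 passed camera, and of 20 unchanged lists 0 did. Simulated genes varied independently of each other and few of them changed. These rates therefore do not show how often camera wrongly calls lists of correlated genes in the real libraries. Alternatives covered the pseudocount, the filter on low values, trimmed-mean (TMM), quantile and total scaling, limma's options, fold thresholds, the replicate number as a block and each library left out in turn.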

Results

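Gene expression was measured by RNA sequencing in primary haematopoietic cells from mouse bone marrow after transduction with an empty vector (3 libraries) or with RUNX1-RARA (3 libraries). The fusion joins RUNX1, a transcription factor of blood cell development, to RARA, the retinoic acid receptor that is rearranged in acute promyelocytic leukaemia, and the comparison asked which genes differed between cells carrying it and vector controls. Each library had between 10375 and 10552 genes at 1 FPKM or more, and estimated depths ran from 26.6 to 89.8 M reads. The libraries separated by group on the first principal component, which held 97.1% of the variance. Across tested genes, which are not independent replicates, the lowest Pearson's r within groups was 0.996, and between-group values lay between 0.851 and 0.857.

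Of the 8 genes with the largest falls in RUNX1-RARA cells, 6 belonged to the fixed list of secondary granule and mature neutrophil genes. Ltf (ENSMUSG00000032496, chromosome 9, 111019271 to 111042767 on mm10), which encodes the granule protein lactoferrin, fell from 1650 ± 35.2 to 2.35 ± 0.0685 FPKM (SD, n = 3 per group), a log2 fold change of -8.94 (SE 0.0503). Gzmb (ENSMUSG00000015437, chromosome 14, 56258838 to 56262260), the gene of the cytotoxic protease granzyme B, rose from 3.52 ± 0.278 to 159 ± 5.67 FPKM, 45.3-fold, and Scin, which encodes the actin-severing protein scinderin, rose 34.3-fold to 332 ± 19.2 FPKM. In all, 8469 of 10901 tested genes passed an adjusted p of 0.05 in limma, 5012 higher and 3457 lower in RUNX1-RARA. At least 2-fold changes on the log2(FPKM + 1) scale were found for 667 higher and 1060 lower genes, so the larger changes were more often falls. The 2 groups did not overlap for 8627 tested genes (79.1%), against 10% by chance. The excess of higher genes was lost under TMM scaling alone: the median log2 fold change of all tested genes was 0.11, TMM scaling shifted it by -0.11, and the calls were then 4108 higher (49.7%) and 4156 lower (50.3%) instead of 59.2% and 40.8%. TMM scaling centres the genes near 0, and under the 3 other scalings between 60.1% and 60.7% of called genes were higher.

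**Figure D1:**
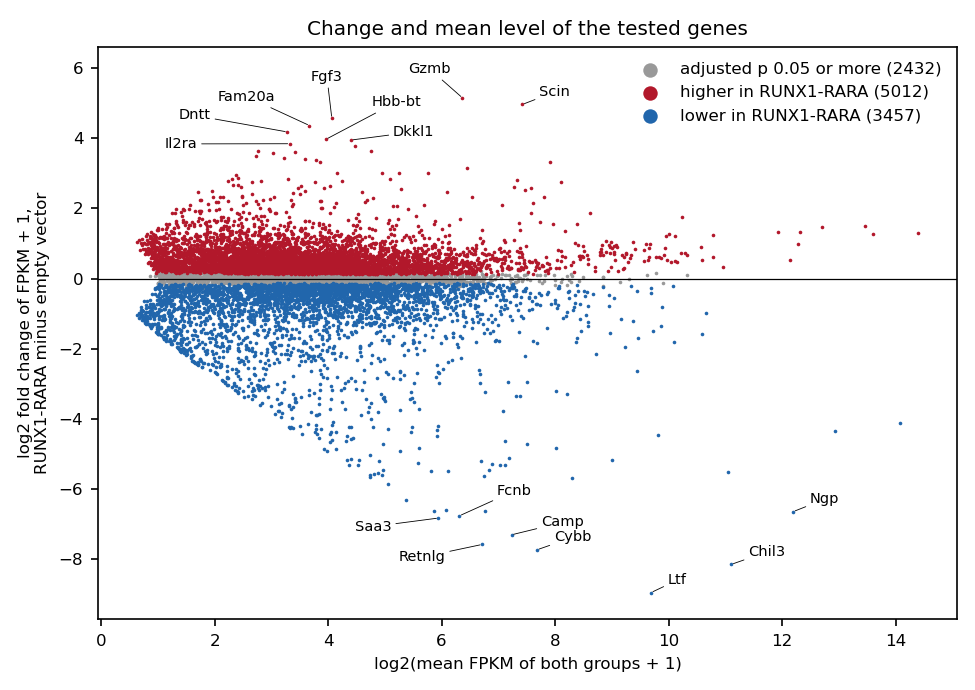
Log2 fold change of FPKM + 1 (vertical axis, RUNX1-RARA minus empty vector) against log2 of the mean FPKM of both groups plus 1 (horizontal axis), 1 point per tested gene, with 5012 higher genes in red, 3457 lower in blue and 2432 others in grey. Falls reach -8.94 (Ltf) and rises 5.15 (Gzmb), with the 8 largest of each direction named.

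The mouse genes of the 2 fusion partners differed little. Runx1 (ENSMUSG00000022952) stood at 17.7 ± 0.993 FPKM in empty vector and 21.9 ± 0.248 FPKM in RUNX1-RARA libraries (SD, n = 3 per group), a log2 fold change of 0.29 (SE 0.0557, limma adjusted p = 6.87e-04). Rara (ENSMUSG00000037992) stood at 12.6 ± 1.33 and 15.4 ± 1.57 FPKM, a log2 fold change of 0.27 (SE 0.089, limma adjusted p = 0.0172). The call of Rara was lost after TMM scaling (log2 fold change 0.16, adjusted p = 0.148) and without empty vector replicate 2 (0.19, adjusted p = 0.0695), RUNX1-RARA replicate 1 (0.26, adjusted p = 0.0511) or RUNX1-RARA replicate 2 (0.21, adjusted p = 0.0646), with adjusted p between 0.004 and 0.148 over all settings. A human fusion transcript need not be counted in these mouse genes, so the values do not measure the fusion itself. Whether some of its reads were counted there is not known, so they need not measure the endogenous genes alone either.

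The 8 largest rises included several genes that were nearly silent in the controls. Fgf3, which encodes a fibroblast growth factor, rose from 0.354 ± 0.0746 to 31.1 ± 0.67 FPKM (SD, n = 3 per group). Fam20a, which encodes a secretory pathway pseudokinase, rose from 0.179 ± 0.0576 to 23.3 ± 1.91 FPKM, and Dkkl1 from 1.57 ± 0.292 to 38.8 ± 6.2 FPKM. Dntt, the terminal transferase of early lymphoid cells, rose from 0.015 ± 0.0135 (0.0095 without empty vector replicate 3) to 17.4 ± 0.554 FPKM, and Il2ra, the interleukin-2 receptor alpha chain, from 0.302 ± 0.016 to 17.7 ± 0.477 FPKM. The globin gene Hbb-bt, whose reads may not have been told from those of its near-identical neighbours, rose from 0.875 ± 0.238 to 28.3 ± 2.39 FPKM. Each of the 8 passed the limma test with an adjusted p of 4.86e-10 or lower. In the whole table, 36 genes were under 1 FPKM in the controls and at 5 FPKM or more in RUNX1-RARA cells, and 172 genes were at 5 FPKM or more in the controls and under 1 FPKM with the fusion.

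**Figure D2:**
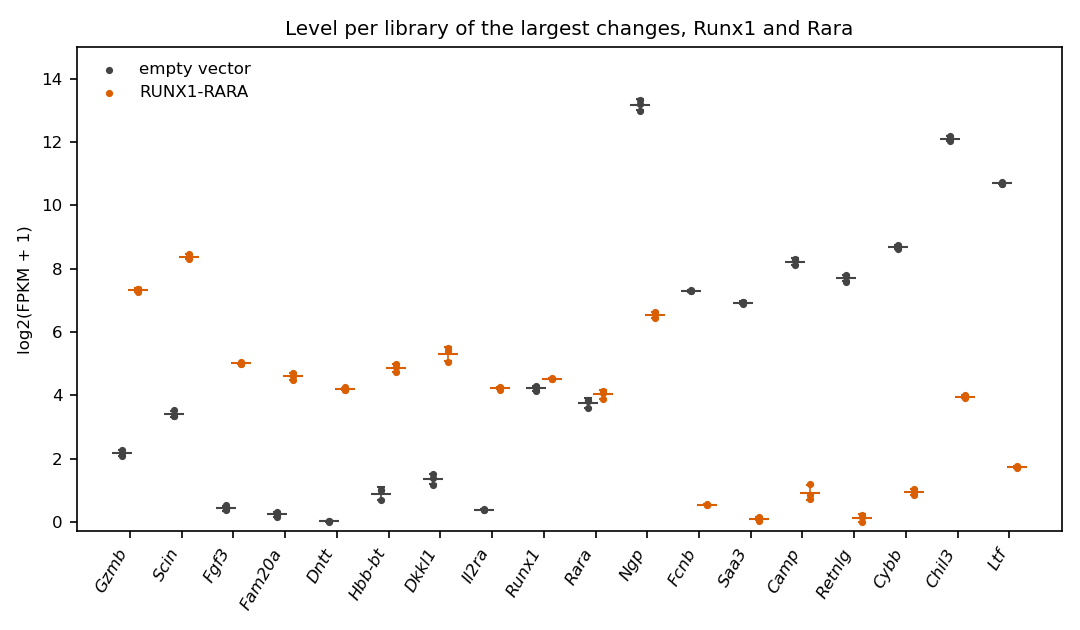
Level of each named gene as log2(FPKM + 1) in the 3 empty vector libraries (grey) and the 3 RUNX1-RARA libraries (orange), with the mean (horizontal bar) and SD (error bar) of the log values. From left to right the genes run from the largest rise (Gzmb, 5.15) to the largest fall (Ltf, -8.94), with Runx1 (0.29) and Rara (0.27) between them.

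All 25 secondary granule and mature neutrophil genes fell, with a median log2 fold change of -5.27. Chil3, a chitinase-like protein of myeloid cells, fell 301-fold from 4398 ± 253 to 14.6 ± 0.596 FPKM (SD, n = 3 per group), Camp, the antimicrobial peptide cathelicidin, 325-fold to 0.918 ± 0.335 FPKM, and Ngp, a neutrophilic granule protein, 101-fold from 9298 to 92.1 FPKM. Retnlg (207.7 to 0.0957 ± 0.0859 FPKM, and 0.0605 FPKM without RUNX1-RARA replicate 3), Fcnb (156.7 to 0.457 FPKM) and Saa3 (121.0 to 0.079 FPKM, not a member of the list) were also among the 8 largest falls. The list took between 15.4% and 16.5% of the FPKM sum in empty vector libraries and between 0.658% and 0.82% in RUNX1-RARA libraries. The list passed camera (adjusted p = 1.25e-17) and also with an estimated correlation (adjusted p = 0.0259), and 25 members passed when adjusted over the list alone.

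Monocyte and macrophage genes fell as well, 17 of 18 tested members, with a median log2 fold change of -2.40. Lyz2, which encodes lysozyme, fell 45.7-fold from 4142 ± 29.9 to 90.7 ± 3.49 FPKM (SD, n = 3 per group). The mannose receptor gene Mrc1 fell from 38.1 ± 1.6 to 0.0767 ± 0.0154 FPKM, and the scavenger receptor gene Msr1 from 18.1 ± 0.215 to 0.002 ± 0.00346 FPKM (0 without RUNX1-RARA replicate 3). The single member that did not pass, Adgre1 (named after its value was seen), stood at 35.8 FPKM in controls and 34.5 FPKM with the fusion. The list passed camera (adjusted p = 2.97e-10) and kept its call with an estimated correlation (adjusted p = 0.0289), and 17 members passed when adjusted over the list alone.

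Related myeloid lists moved the same way, but none of their calls held with an estimated correlation. All 6 NADPH oxidase genes fell, among them Cybb, the catalytic subunit of the phagocyte oxidase, 435-fold from 408 ± 17.6 to 0.938 ± 0.14 FPKM (SD, n = 3 per group), Ncf1, 10.4-fold, and Ncf4, 3.74-fold (camera adjusted p = 1.85e-04, adjusted p = 0.105 with an estimated correlation). Of 15 granulocyte and monocyte transcription factors, 10 fell and 5 rose. Klf4 (3.92 to 0.0613 FPKM), Cebpb (22.7 to 4.85 FPKM) and Spi1, the gene of PU.1 (68.8 to 19.7 FPKM), fell most (camera adjusted p = 0.0154, adjusted p = 0.139 with an estimated correlation). Eosinophil genes split 6 lower to 2 higher, with Prg2, a granule major basic protein, 44.2-fold lower, Ear2 at 18.8 and 0.0347 ± 0.06 FPKM (0 without RUNX1-RARA replicate 1) and Epx, the eosinophil peroxidase, 125-fold lower (camera adjusted p = 0.0133, adjusted p = 0.139 with an estimated correlation). All 5 tested dendritic cell and antigen presentation genes fell, including the class II gene H2-Aa 7.14-fold, Cd74 5.76-fold and H2-Eb1 5.99-fold (camera adjusted p = 0.0018, adjusted p = 0.105 with an estimated correlation).

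Primary granule and promyelocyte genes split instead of falling together: 5 rose and 7 fell of 12, and the list was not called (camera adjusted p = 0.37). The neutrophil elastase gene Elane fell 9.39-fold from 467 ± 38.7 to 49.7 ± 7.96 FPKM (SD, n = 3 per group), the proteinase 3 gene Prtn3 4.68-fold and Ctsc, which activates granule proteases, 2.97-fold. Of genes chosen after their values were seen, Ctsg, the cathepsin G gene, rose from 598 to 1456 FPKM, while Mpo, the myeloperoxidase gene, fell from 940 to 707 FPKM. Mast cell and basophil genes also split, 5 higher and 6 lower of 14 (camera adjusted p = 0.545). Besides the rise of Gzmb, the IgE receptor gene Fcer1a fell 98.0-fold from 57.1 to 0.582 FPKM and the basophil protease gene Prss34 39.3-fold from 283 to 7.21 FPKM.

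Targets of the 2 fusion partners were mostly lower. Of 7 tested retinoic acid response genes, 6 fell and 1 rose (median log2 fold change -1.21). Cd38 fell from 21.2 ± 0.909 to 0.0253 ± 0.0234 FPKM (SD, n = 3 per group, and 0.015 FPKM without RUNX1-RARA replicate 1), Asb2, a ubiquitin ligase subunit, 66.6-fold and Dhrs3, a retinaldehyde reductase, 6.32-fold. The list passed camera (adjusted p = 0.00374) but not with an estimated correlation (adjusted p = 0.113). Of 11 tested RUNX1 targets of myeloid and megakaryocytic cells, 8 fell and 2 rose, led by Elane, by the platelet chemokine gene Pf4, 9.23-fold lower, and by the macrophage growth factor receptor gene Csf1r, 8.75-fold lower from 30.2 ± 0.304 FPKM. That list passed camera (adjusted p = 0.0177) but not with an estimated correlation (adjusted p = 0.347).

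Stem and progenitor genes changed in both directions, 12 higher and 6 lower of 18, and the list was not called (camera adjusted p = 0.25). Cd34, a surface marker of progenitors, rose 9.27-fold from 16.8 ± 0.556 to 155 ± 1.15 FPKM (SD, n = 3 per group), and Adgrg1, which encodes an adhesion receptor, 8.05-fold to 58.8 ± 9.32 FPKM. Ly6a, which encodes the stem cell antigen Sca-1, fell 9.14-fold to 4.18 ± 0.373 FPKM. Megakaryocyte genes were 3 higher and 3 lower of 6 (camera adjusted p = 0.38), with the platelet basic protein gene Ppbp 58.3-fold and Gp1bb 79.8-fold lower. Reads of Gp1bb may not have been told from those of the overlapping Septin5, which went from 25.2 to 0.347 FPKM, and Gm49601, which went from 30.2 to 0.447 FPKM. Erythroid genes were 4 higher and 1 lower of only 5 tested (camera adjusted p = 0.158), with Hemgn 7.36-fold and Car2, a carbonic anhydrase, 3.12-fold higher beside Hbb-bt.

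All 18 MYC target and ribosome biogenesis genes rose, with a median log2 fold change of 0.70. Ppan rose 2.93-fold from 17.2 ± 0.983 to 50.4 ± 3.82 FPKM (SD, n = 3 per group), the nucleolar gene Gnl3 2.24-fold and the spermidine synthase gene Srm 2.23-fold. All 13 mitochondrially encoded genes rose too (median log2 fold change 1.3), among them mt-Nd3 5.05-fold, mt-Co3 2.94-fold and mt-Nd4l 2.91-fold. They took between 7.96% and 10.6% of the FPKM sum in empty vector libraries and between 21.9% and 26.3% with the fusion. Both lists passed camera (adjusted p = 8.43e-05 for MYC targets and 0.00187 for mitochondrially encoded genes) and lost the call with an estimated correlation (adjusted p = 0.105 and 0.347).

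Inflammatory and stimulus-response lists were lower. Of 19 interferon response genes 16 fell and 2 rose, with Ifi27l2a 7.8-fold, Cmpk2 8.21-fold and Oasl2 9.88-fold lower (camera adjusted p = 4.42e-05, adjusted p = 0.172 with an estimated correlation). Without RUNX1-RARA replicate 1, the fall of Ifi27l2a was 12.96-fold. Of 15 NF-kB and cytokine genes 11 fell and 1 rose. The interleukin-1 beta gene Il1b fell 11.1-fold from 28.5 ± 0.375 FPKM (SD, n = 3 per group), and the chemokine genes Ccl3 and Ccl4 fell 8.36-fold and 5.73-fold (camera adjusted p = 0.00171, adjusted p = 0.105 with an estimated correlation). Of 14 immediate early and heat shock genes 9 fell and 2 rose, with Fos 5.97-fold, Zfp36 4.23-fold and Atf3 7.6-fold lower (camera adjusted p = 0.0129, adjusted p = 0.297 with an estimated correlation). Of 11 coagulation and fibrinolysis genes, a group of clinical interest in promyelocytic leukaemia, 8 fell and 2 rose. The coagulation factor genes F10 and F5 fell 10.4-fold and 5.05-fold and the urokinase receptor gene Plaur 6.61-fold (camera adjusted p = 0.00965, adjusted p = 0.172 with an estimated correlation).

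Of 18 mitosis genes 9 fell and 1 rose (median log2 fold change -0.15), with Aurka 1.49-fold, Plk1 1.43-fold and Nusap1 1.35-fold lower. The call of this list (camera adjusted p = 0.035) was lost without empty vector replicate 2 (adjusted p = 0.0619), RUNX1-RARA replicate 1 (adjusted p = 0.0603) or RUNX1-RARA replicate 2 (adjusted p = 0.0682), after quantile normalization (adjusted p = 0.137), after rescaling to equal sums (adjusted p = 0.0603) and with an estimated correlation (adjusted p = 0.355). After TMM scaling 13 fell and 0 rose (median -0.27, camera adjusted p = 0.0142), and without RUNX1-RARA replicate 3 the counts were 11 and 1 (adjusted p = 0.018). Over all camera settings its adjusted p ran from 0.0142 to 0.355, and fry, which tests against no change, gave 0.00315. DNA replication genes were 5 higher and 3 lower of 18 (camera adjusted p = 0.703), with the ribonucleotide reductase gene Rrm2 1.76-fold and Slbp 1.44-fold lower and the thymidylate synthase gene Tyms 1.58-fold higher. After TMM scaling these counts became 2 and 8.

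The remaining lists with a lineage or stress theme were not called, apart from that of T and NK cells. Of 13 p53 targets 10 rose and 2 fell (camera adjusted p = 0.158), with Zmat3 2.96-fold higher and the death receptor gene Fas 6.55-fold and Trp53inp1 2.08-fold lower. Unfolded protein and amino acid stress genes were 7 higher and 1 lower of 14 (camera adjusted p = 0.25), with Trib3 (3.57 to 14.3 FPKM), Ddit3 (1.73-fold) and Psat1 (1.65-fold) higher. Glycolysis and hypoxia genes were 2 higher and 10 lower of 16 (camera adjusted p = 0.112), with Vegfa 2.46-fold and Ankrd37 1.81-fold lower and Egln3 1.69-fold higher. Cholesterol synthesis genes were 6 higher and 5 lower of 20 (camera adjusted p = 0.924), with Hsd17b7 2.14-fold and Sc5d 1.74-fold lower, and 5 and 8 after TMM scaling. Genes of m6A methylation, the RNA modification named in the labels, were 6 higher and 1 lower of 14 (camera adjusted p = 0.604), with Fto 1.7-fold, Mettl3 1.49-fold and Cbll1 1.35-fold higher, and 4 and 5 after TMM scaling.

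Markers of other cell types were mostly too low to test. Of 13 T and NK cell genes 3 were tested and rose, Tcf7 from 0.349 to 7.6 FPKM, Lck from 0.655 to 3.03 FPKM and Gata3 from 0.0433 to 1.43 FPKM (camera adjusted p = 0.0294). All 3 were under 1 FPKM in every control and passed the filter only through the RUNX1-RARA libraries, so the filter itself favoured a rise. This call was lost with an estimated correlation (adjusted p = 0.231) and when low genes were kept (adjusted p = 0.502), and its adjusted p ran from 0.0177 to 0.502 over all camera settings (7.41e-06 with fry, which tests against no change). Of 14 B cell genes 2 were tested, 1 higher (Dntt) and 1 lower (Cd79b). Of 15 stromal and endothelial genes 2 were tested and both rose, Pdgfrb and Pecam1, while the stromal collagen genes Col1a1, Col1a2 and Col3a1 stayed under 1 FPKM in both groups (genes of these short lists were named after their values were seen).

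Camera called 16 of the 27 tested lists, 3 higher and 13 lower. With an estimated correlation only the calls of mature neutrophil genes and of monocyte and macrophage genes held. The estimates for these 2 lists were 0.0128 and 0.00342, near the preset 0.01. Their camera adjusted p nevertheless rose from 1.25e-17 to 0.0259 and from 2.97e-10 to 0.0289. NADPH oxidase (-0.149) and retinoic acid response genes (-0.0697) had negative estimates and still lost their calls. Mitochondrially encoded genes had a high one (0.415). A call lost in this setting therefore need not mean that correlated genes had made it. Changing the filter on low values added calls: higher stem and progenitor genes and erythroid genes at a minimum of 5 FPKM, and lower megakaryocyte genes and higher p53 targets when low genes were kept. In 27 of the 29 lists as many members passed when adjusted over the list alone as over all tested genes. The exceptions were unfolded protein and amino acid stress genes, with 7 adjusted over the list alone, and m6A methylation genes, with 6 adjusted over the list alone, each 1 fewer.

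**Figure D3:**
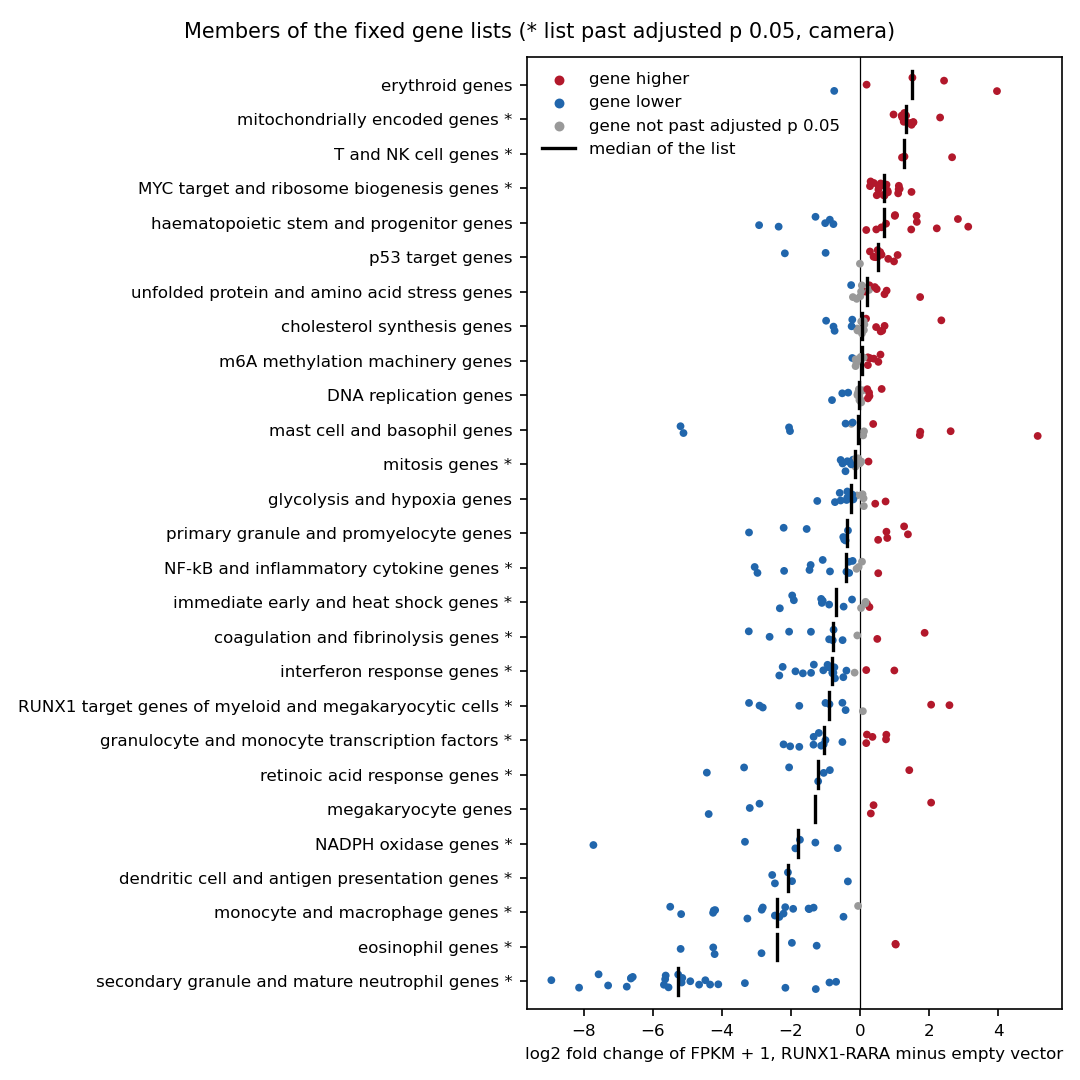
Log2 fold change of FPKM + 1 (horizontal axis, RUNX1-RARA minus empty vector) of each tested member of the 27 tested gene lists (1 line each), with red points for genes higher, blue for lower and grey for genes not past an adjusted p of 0.05, a black bar at the list's median and a star for the 16 lists past an adjusted p of 0.05 in camera. The medians run from -5.27 (mature neutrophil genes) to 1.52 (erythroid genes).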

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

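All alternatives were planned except the totals without the 50 highest genes, which was chosen after seeing the data. Fold thresholds moved the counts most. With a 2-fold minimum, 1727 genes passed, 667 higher and 1060 lower. Tested against a 1.2-fold change with limma's treat, 5227 passed, 2945 higher and 2282 lower. Camera called 2 lists with an estimated correlation, and fry, which does not compare a list with other genes, called 26. Rara lost its call after TMM scaling (log2 fold change 0.16), and with each library left out in turn it ran from 0.19 to 0.35. The causes were not tested. No called value reversed its direction (the uncalled DNA replication, cholesterol and m6A lists had medians near 0 that changed sign with scaling). The other named genes, with Runx1, kept their calls under every setting in which they were tested. The fold thresholds and a stricter adjusted p of 0.01 were applied to the gene counts only. Small changes such as that of Runx1 lie under the 2-fold minimum. The T and NK list had too few members at a minimum of 5 FPKM to be tested there. Replicate numbers did not pair the samples (correlation of same-numbered deviations 0.02, -0.37 and -0.06), and no library correlated best with its own number. The highest values were 0.40 (empty vector replicate 2 with RUNX1-RARA replicate 3), 0.36 (replicate 1 with replicate 2) and 0.10 (replicate 3 with replicate 1). With the replicate number as a block 8230 genes and 15 lists were called, against 8469 and 16 without it, and the mitosis list lost its call. Count tests on recovered reads were planned and not run, because whole reads were recovered only in part. Depth limits levels near the value of 1 read, at most 0.0188 FPKM for a 2 kb transcript.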

Other observations

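The gene families, the Hox genes and the other single genes described first were chosen after seeing the data, and so were the tests of a neutrophil loss alone, of T or NK cells and of short transcripts. Of the Hoxa genes on chromosome 6 that were above 0 in empty vector libraries, 8 were listed at 0 in all 3 RUNX1-RARA libraries. Most of these were low in the controls too, with 6 of the 8 at means between 0.0483 and 0.593 FPKM and so below the filter of 1 FPKM. Of the other two, Hoxa9 went from 4.14 ± 0.529 FPKM (SD, n = 3) to a listed value of 0, and Hoxa7 from 1.45 ± 0.174 FPKM to 0. On chromosome 11, Hoxb4 went from 6.5 ± 0.852 to 0.788 ± 0.191 FPKM. Meis1, a partner of Hox proteins, fell from 1.48 to 0.236 FPKM, while Mycn rose from 2.58 to 15.8 FPKM. The neighbouring receptor genes Pdgfrb and Csf1r on chromosome 18 moved apart, Pdgfrb from 0.603 ± 0.0551 to 18.7 ± 1.59 FPKM and Csf1r from 30.2 ± 0.304 to 3.45 ± 0.495 FPKM.

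Of 16 added families, 12 passed camera and none held with an estimated correlation. As for the fixed lists, a call lost this way need not mean that correlated genes had made it. Of 79 cytosolic ribosomal protein genes 78 rose (median log2 fold change 0.69, adjusted p = 0.392 with an estimated correlation), and 15 of 18 aminoacyl-tRNA synthetase genes rose (0.47, adjusted p = 0.363 with an estimated correlation), as did all 8 chaperonin genes (0.50, adjusted p = 0.468 with an estimated correlation). Of 11 cathepsin genes 9 fell and 1 rose (-1.51, adjusted p = 0.0998 with an estimated correlation), and 7 of 8 Toll-like receptor genes fell (-2.59, adjusted p = 0.161 with an estimated correlation). All 8 MS4A genes fell (-2.31, adjusted p = 0.0998 with an estimated correlation), and 14 of 18 V-ATPase genes, which acidify lysosomes and granules, fell (-0.59, adjusted p = 0.126 with an estimated correlation). These medians kept their sign under all 5 scalings tried, and after TMM scaling 13 synthetase genes rose and 1 fell.

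The first pattern is the joint rise of mitochondrially encoded and MYC target genes. It was chosen after the list counts, medians and camera results on the deposited FPKM had been seen. The tests of scaling, poly(A) selection and a general rise were set then, before the values that decide them were computed. The tables argue against a scaling shift: after TMM scaling the median log2 fold change of the mitochondrially encoded genes was still 1.2 with 13 of 13 called, and that of MYC targets 0.58 with 18 of 18 called. Nuclear genes of mitochondrial proteins rose far less. Those of oxidative phosphorylation had a median of 0.11 (95% bootstrap interval 0.07 to 0.20, 31 higher and 12 lower of 80 genes) and of -0.01 after TMM scaling (23 and 18). Those of mitochondrial ribosomal proteins had a median of 0.25 (54 higher and 8 lower of 78 genes, camera adjusted p = 0.00553, adjusted p = 0.468 with an estimated correlation), and of 0.14 after TMM scaling (36 and 12). A general rise as large as that of the mitochondrially encoded genes is thus excluded, and a small one stays open. A bias toward short transcripts would raise short genes as a class, but over all tested genes, those that rose included, the median of genes with exons under 1 kb differed from that of longer ones by only -0.00189 (interval -0.05 to 0.12, 330 short genes). Weaker poly(A) selection in the RUNX1-RARA libraries, if these were selected at all, stays open for the mitochondrially encoded genes. Histone mRNAs, which lack poly(A) tails, rose as well (median 0.78, interval 0.44 to 0.90, 26 genes, camera adjusted p = 0.119 with an estimated correlation). The tails of the mitochondrially encoded mRNAs were not measured, so the histone rise does not show that selection raised them. MYC target mRNAs carry poly(A) tails, so weaker selection does not cover them, and what raised them stays open. An effect of the fusion on ribosome production may be a cause, as a hypothesis that these tables do not test and that the rate of ribosomal RNA synthesis with the fusion switched off would.

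The second pattern is the fall of mature neutrophil and monocyte genes. A lower share of neutrophils alone would raise the genes of all other cells. Dendritic cell and antigen presentation genes, a separate list, fell instead (median log2 fold change -2.09, 95% bootstrap interval -2.54 to -0.35, 5 genes). All 5 were known to be lower when this test was chosen, and the interval is only their own range, so it adds no support. Their values argue against a loss of neutrophils alone for these 5 genes. The monocyte and macrophage genes of the pattern itself fell too, 17 of 18 with 0 higher (median log2 fold change -2.40). Eosinophil genes split 6 lower to 2 higher. For the genes that fell in these lists, the values also argue against a loss of neutrophils alone. Fewer mature cells of both kinds, or lower expression within cells, stay open and cannot be separated in bulk libraries. Cells held at an earlier stage by the fusion may explain both, as a hypothesis, although Ctsg rose while Elane and Prtn3 of the same granules fell. Sequencing of single cells would test this, since a block changes the numbers of cells per stage and lower expression within cells does not.

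The third pattern is the rise of Dntt, Il2ra, Tcf7 and Gzmb, 4 genes grouped after their values were seen because lymphoid cells use them. Support for a wider lymphoid rise is weak: the T and NK list was called higher, but on 3 genes that passed the filter only through the RUNX1-RARA libraries, and it lost its call with an estimated correlation and when low genes were kept. Of the B cell list, 1 tested gene was higher and 1 lower. T or NK cells in the RUNX1-RARA cultures would bring their abundant transcripts, but of Cd3e, Cd3d, Cd3g, Lck, Cd2, Klrd1 and Ncr1 only 1 of 7, Lck, reached 1 FPKM. Cd3e, Cd2 and Ncr1 were listed at 0 in all 3 libraries, Cd3d was at 0.045 FPKM, Klrd1 at 0.691 ± 0.194 FPKM and Cd3g close to the limit at 0.968 ± 0.287 FPKM. These 7 genes were chosen for T and NK cells and do not test for early lymphoid cells, in which Dntt is used. Such cells therefore stay open. Expression of Dntt, Il2ra, Tcf7 and Gzmb within other transduced cells may be a candidate explanation and was not tested. Gzmb also belongs to the fixed mast cell list, so it does not mark lymphoid cells alone.

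Other divisions of the 6 libraries 3 against 3 are too few, 10 in all, to give a share under 0.05. The real division gave 8469 genes in limma, 5012 higher and 3457 lower, and 1 of the 10 divisions reached these counts, the real one. The highest count in any other division was 0. Every other division mixes both groups, so the group difference, on a component with 97.1% of the variance, counts there as spread. Low counts in these divisions were thus fixed in advance and add no support.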
